A study of Mus musculus with 6 samples.

How the data were processed

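RNA was sequenced from the visual cortex of male C57BL/6J mice at postnatal day 14. There were 6 libraries, 3 of them from knockouts of *Chrdl1* (KO) and 3 from wild type (WT). Per the labels' protocols, the animals were perfused with paraformaldehyde before the cortex was taken, RNA was purified on silica columns, and libraries were made with a stranded mRNA kit. The labels do not say in words that each library is a separate animal, so the p-values measure the spread between these libraries. Genotype was taken from the labels, and the replicate number from the middle number of each library title.

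The authors deposited 1 table of FPKM values (fragment values scaled by exon length and by the mapped reads of the library) with 24453 gene rows and 6 library columns, made with the HOMER command recorded in its header. Per the file headers, reads were counted over exons with all transcripts of a gene condensed to 1 row on mm10. Per the submitters' processing notes, STAR 2.4.0k, HOMER 4.8.3 and FastQC were used. The command names 12 libraries, of which 6 have columns, and the others are not analysed here. It names no strand option, so whether the counting used the strand is not known, and values of overlapping or antisense genes are uncertain. Families with near-identical copies (globins, ribosomal proteins) are uncertain too. FPKM sets each library to the same number of mapped reads, so only relative levels can be compared.

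Depth was recovered from the FPKM values, which rise in steps of 1 read. With the best total per library, 100.0% of the values checked were whole within 0.1 read. These were nonzero values under 200 reads in genes short enough that rounding of the FPKM could not hide a step, 4897 to 7147 per library. Whole reads were not checked in longer genes. Estimated totals (M, megareads) were 38.2, 27.5 and 34.0 M for WT replicates 1, 2 and 3, and 26.4, 22.7 and 31.9 M for KO replicates 1, 2 and 3. Of these, 84.8% to 87.0% fell in genes. For a gene of 2000 bp, a count of 0 (3 counts as the upper limit) allows up to 0.0393 FPKM in the deepest library and 0.0662 in the shallowest. Such limits, and the read intervals, cover counting error only.

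The main test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), 2-sided, with an intensity trend in the empirical Bayes step, on the 12863 genes with a mean of 1 FPKM or more. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. All log2 fold changes are KO minus WT on this scale, which understates changes of low genes. Gene lists were tested with camera in limma at a preset correlation of 0.01, then with an estimated correlation, and with fry, adjusted over 34 lists. These covered glutamate and GABA synapses, BMP signalling, astrocytes, other cell types, neighbouring brain regions, immediate early genes, perineuronal nets, stress, cholesterol synthesis, ribosomal proteins, sex-linked genes and X-linked neighbours of *Chrdl1*. A list of mitochondrially encoded genes had no member in the table. Of 735 list entries, 719 matched a symbol of the table, 2 an older symbol and 14 none. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

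The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes *Chrdl1*, in each direction the 10 genes with the largest change among called genes without overlap (filled by smallest unadjusted p), every AMPA receptor subunit, and the members with the smallest unadjusted p from each list, up to 4 from the lists on AMPA receptor trafficking, NMDA receptors, BMP signalling, astrocytes, immediate early genes and perineuronal nets and up to 2 from the others. Genes named outside it were chosen after their values were seen, and 1 gene that the rule takes is not reported here.

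Libraries that share a number in their titles deviated together. The correlation of their deviations from the group means over tested genes was 0.43, 0.71 and 0.67 for numbers 1, 2 and 3, against -0.61 to -0.06 for the other pairings. By the rule set in advance (over 0.1 in every pair) the numbers pair the libraries, although the labels do not say what a number stands for. A fit with the number as a replicate block was therefore run as an alternative, and its value stands beside a result where it changes a call. No duplicate libraries were found, since the chi-square per degree of freedom between libraries was 2.8 at the lowest.

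The gene test was tested on simulated data with the real gene means and pair effects and 200 of the 12863 genes changed by known folds. In the KO against WT comparison it called 0, 21, 41 and 50 of 50 genes changed by 1.25, 1.5, 2 and 4 times, with 2 false calls, and the blocked fit called 11, 38, 46 and 50, with 4 false calls. The simulated variances were drawn from the fitted prior. In an earlier version that took the shrunken variances as the truth, the blocked fit made 36 false calls, 16.5% of its calls, and that version was replaced. Alternatives covered the pseudocount, the filter, rescaling, the variance model, library weights, the block, leaving out each library, and settings added after seeing the data: voom on the recovered reads, short rows left out, both libraries of a number left out, and the striatal list as a covariate.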

Results

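The series profiled messenger RNA in the visual cortex of 14-day-old male mice that lacked *Chrdl1* or were wild type, with 3 libraries per genotype. *Chrdl1* encodes chordin-like 1, a secreted antagonist of bone morphogenetic proteins (BMPs) that astrocytes make and that has been linked to the synaptic recruitment of the AMPA receptor subunit GluA2. The comparison asks which transcripts differ in the cortex without it. Estimated depth was 33.2 ± 5.4 megareads (SD, n = 3) in WT and 27.0 ± 4.6 megareads (SD, n = 3) in KO, and the KO library was the shallower one in each pair with the same title number.

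*Chrdl1* fell in the KO cortex from 3.44 ± 0.299 to 0.161 ± 0.036 FPKM (SD, n = 3 per genotype), which is 4.67% of the WT level. The 3 WT libraries held 582, 410 and 440 reads of the gene and the 3 KO libraries 19, 18 and 16. The log2 fold change was -1.93 (SE 0.09), with a limma adjusted p of 0.000489. An exact 2-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The gene (NM_031258) lies on the minus strand of chromosome X in mm10, from 143297158 to 143394262 in the authors' model, with 4179 bp of exon. The remaining KO reads cannot be placed within the gene, since the table gives 1 value per gene. The low level in each KO library goes with its label. With both libraries numbered 1 or both numbered 2 left out, a test of 4 libraries chosen after seeing the data, the fold change stayed at -1.91 and -1.93, but the adjusted p was 0.244 and 0.0906. With both numbered 3 left out the gene was called (-1.96, limma adjusted p 0.0277).

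**Figure D1:**
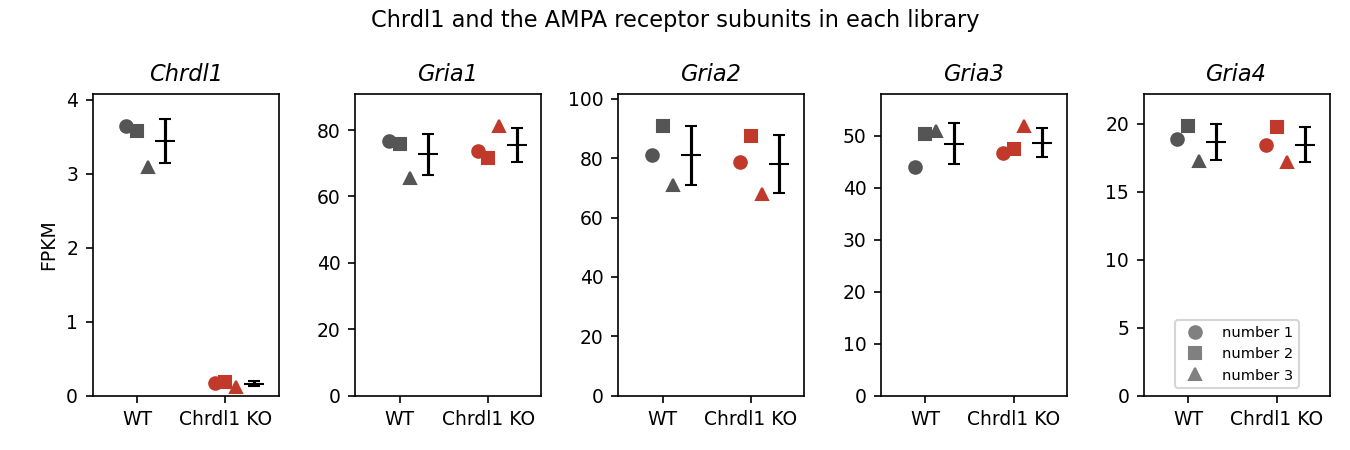
Levels of *Chrdl1* and the AMPA receptor subunits in FPKM (vertical axes from 0) in each WT (grey) and KO (red) library, with symbols for the title number and bars for the mean ± SD (n = 3). *Chrdl1* lies between 3.09 and 3.65 in WT and between 0.12 and 0.19 in KO, while the values of each *Gria* gene overlap between genotypes, with *Gria2* and *Gria4* slightly lower in the KO library of each pair.

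*Chrdl1* was the only gene called among 12863, with 0 genes higher and 1 lower by limma at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 81 genes, against 643 by chance, and 503 with the replicate block. The main fit has no block, so differences between the paired numbers enter its error. Its median SE was 0.0968, against 0.0576 with the block, and its p-values run high for paired libraries. The lowest adjusted p of another gene was 1, or 0.235 with the block. The KO and WT values did not overlap for 379 genes (2.9%), where chance gives 10% for exchangeable libraries, which these paired ones are not. Within pairs, KO was higher in 3 of 3 for 12.3% of genes and in 0 of 3 for 9.6%, where chance gives 12.5%. On the log2(FPKM + 1) scale, the 95% interval lay within 1.5-fold of no change for 95.9% of genes and within 2-fold for 99.2%, which does not limit the change in FPKM of genes near 1 FPKM. Limma on reads recovered from the FPKM values, added after seeing the data, also called 1 gene, and 2 with the block.

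None of the 4 AMPA receptor subunit genes passed the test, over all genes or adjusted over the list alone. *Gria2*, which encodes GluA2, measured 81.0 ± 9.97 FPKM in WT and 78.0 ± 9.88 in KO (SD, n = 3), with a log2 fold change of -0.05 and a 95% interval of -0.34 to 0.23. *Gria1*, which encodes GluA1, measured 72.7 ± 6.16 and 75.5 ± 5.07 FPKM (log2 fold change 0.06, interval -0.15 to 0.26). *Gria3* stood at 48.4 ± 3.93 and 48.7 ± 2.82, and *Gria4* at 18.6 ± 1.31 and 18.4 ± 1.28. Within pairs, *Gria2* and *Gria4* were each lower in KO in 3 of 3, a direction that 12.5% of genes show by chance, and neither passed with the block, where the interval of *Gria2* was -0.14 to 0.03 (limma adjusted p = 0.999).

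Other genes of the glutamate synapse did not pass either. Of 24 genes for AMPA receptor auxiliary and trafficking proteins, 0 were called over all genes or adjusted over the list alone. They included the neuronal pentraxin *Nptx2* at 23.8 ± 4.12 FPKM in WT and 21.6 ± 2.16 in KO, *Porcn*, *Grip2* and *Shisa6*, with log2 fold changes of -0.13, -0.08, -0.10 and 0.12. Of 7 NMDA receptor subunit genes, 0 were called. The obligatory subunit gene *Grin1* measured 133 ± 4.86 and 137 ± 11.6 FPKM, and *Grin3a*, *Grin3b* and *Grin2c* had log2 fold changes of 0.07, -0.04 and 0.04. Among 12 kainate and metabotropic receptor genes, 0 were called without the block, and 1 was called adjusted over the list alone with it: *Grm2*, a presynaptic metabotropic receptor gene, at 18.9 ± 0.981 and 22.4 ± 2.58 FPKM (log2 fold change 0.22, adjusted p over the list 0.582 without and 0.0425 with the block, limma). *Grm8* was at 0.11. The lists of 20 postsynaptic scaffold genes (*Homer3* 0.12, *Homer1* -0.09) and 23 presynaptic release genes (*Slc17a6* 0.10, *Bsn* 0.10) had 0 called members.

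The 19 measured GABA synapse genes were lower as a group by camera, with a median log2 fold change of -0.03 and adjusted p = 0.0311. The adjusted p was 0.669 with an estimated correlation. Of these genes 14 were lower and 5 higher, and 0 were called, over all genes or over the list alone. *Gabrd*, an extrasynaptic GABA receptor subunit gene, measured 30.1 ± 2.65 FPKM in WT and 27.5 ± 2.89 in KO, and *Gad2*, a GABA-synthesising enzyme gene, 37.6 ± 3.32 and 34.5 ± 3.30. Within pairs the median was -0.08, -0.01 and 0.00 for numbers 1, 2 and 3, so of the pairs in which the striatal markers described below were lower (1 and 3) it was lower in number 1. With the mean of those markers as a covariate the median of the GABA list became 0.05.

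BMP signalling genes did not pass. Of 19 measured genes for BMP ligands, receptors and Smads, 0 were called. *Bmp6*, a ligand gene, measured 2.30 ± 0.318 FPKM in WT and 2.86 ± 0.023 in KO (log2 fold change 0.23, limma unadjusted p = 0.0434, adjusted p = 1), and *Bmp7*, *Acvr1* and *Smad1* had log2 fold changes of 0.14, -0.09 and -0.08. Of 7 measured BMP target genes, 0 were called. *Id1* stood at 11.4 ± 1.29 and 10.5 ± 0.798 FPKM and *Id2* at 90.3 ± 4.85 and 94.4 ± 3.87. *Smad9* and *Hey1* were at -0.04 and -0.03. Of 9 measured genes for other BMP antagonists, 0 were called, with *Twsg1* at 0.17, *Crim1* at 0.12, *Bmper* at 0.10 and *Nog*, which encodes noggin, at -0.15. Camera called none of these 3 lists (adjusted p 0.94, 0.485 and 0.0976).

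Astrocyte genes were close between genotypes. Of 18 astrocyte markers 0 were called: *Aldh1l1* measured 21.8 ± 1.89 FPKM in WT and 23.5 ± 1.89 in KO, *Gfap* 47.8 ± 4.29 and 51.0 ± 4.64, and the glutamate transporter genes *Slc1a2* and *Slc1a3* had log2 fold changes of 0.06 and 0.06. The 15 measured genes for secreted synapse regulators were higher as a group by camera (median 0.06, 12 higher and 3 lower, adjusted p = 0.0297, and adjusted p = 0.291 with an estimated correlation). The meningeal, pericyte and endothelial lists were higher in the same comparison, with medians of 0.22, 0.09 and 0.05. Within the pairs numbered 1, 2 and 3 the median of the regulators was 0.06, 0.06 and 0.14. The meningeal list had pair medians of 0.34, -0.03 and 0.22. Those of the pericyte list were 0.14, 0.01 and 0.13, and those of the endothelial list 0.09, 0.07 and 0.09. None of the secreted regulators was called alone, and *Thbs1*, *Thbs2*, *Tgfb1* and *Sparcl1* stood at 0.16, 0.15, 0.12 and 0.10. Of 14 measured reactive astrocyte genes, 0 were called without the block. With it, *Psmb8*, an immunoproteasome subunit gene, was called adjusted over the list alone (1.46 ± 0.187 and 0.976 ± 0.116 FPKM, adjusted p over the list 0.179 without and 0.0402 with the block, limma). *Tm4sf1*, *Vim* and *Cp* were at 0.14, 0.11 and 0.16.

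Genes of activity and of cortical maturation did not pass. Of 27 measured immediate early genes 0 were called, with *Pim1* at -0.17, *Dusp6* at -0.13 and *Jun* at 0.12. The median of this list was 0.01 while camera's direction was down, with an adjusted p of 0.891. Its direction depended on single libraries: it was called higher without WT replicate 3 (median 0.179) and with array weights (0.162), and lower without WT replicate 1 (-0.111) and without KO replicate 3 (-0.117). Of 16 measured genes of perineuronal nets and the critical period 0 were called. *Pvalb*, the parvalbumin gene, varied widely between libraries, at 23.3 ± 10.3 FPKM in WT and 21.1 ± 8.60 in KO, and *Crtac1*, *Bcan* and *Rtn4* were at 0.08, 0.05 and -0.06. Lists of 14 stress genes (*Cdkn1a* 0.09, *Hspa8* 0.04), 18 cholesterol synthesis genes (*Sc5d* -0.08, *Srebf2* 0.05) and 58 ribosomal protein genes (*Rps25* -0.28, *Rps27l* -0.24) had 0 called members. The ribosomal protein values are uncertain, since how the counting treated reads that match near-identical copies is not given in the sources used here. Of 86 measured neighbours within 10 Mb of *Chrdl1* 0 were called, with a median of -0.01 (*Armcx4* 0.18, *Mir7646* -0.31). All 6 libraries expressed Y-linked genes, such as *Eif2s3y* (15.7 ± 1.44 and 17.8 ± 2.11 FPKM) and *Kdm5d* (0.05), and *Xist* reached at most 0.006 FPKM.

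**Figure D2:**
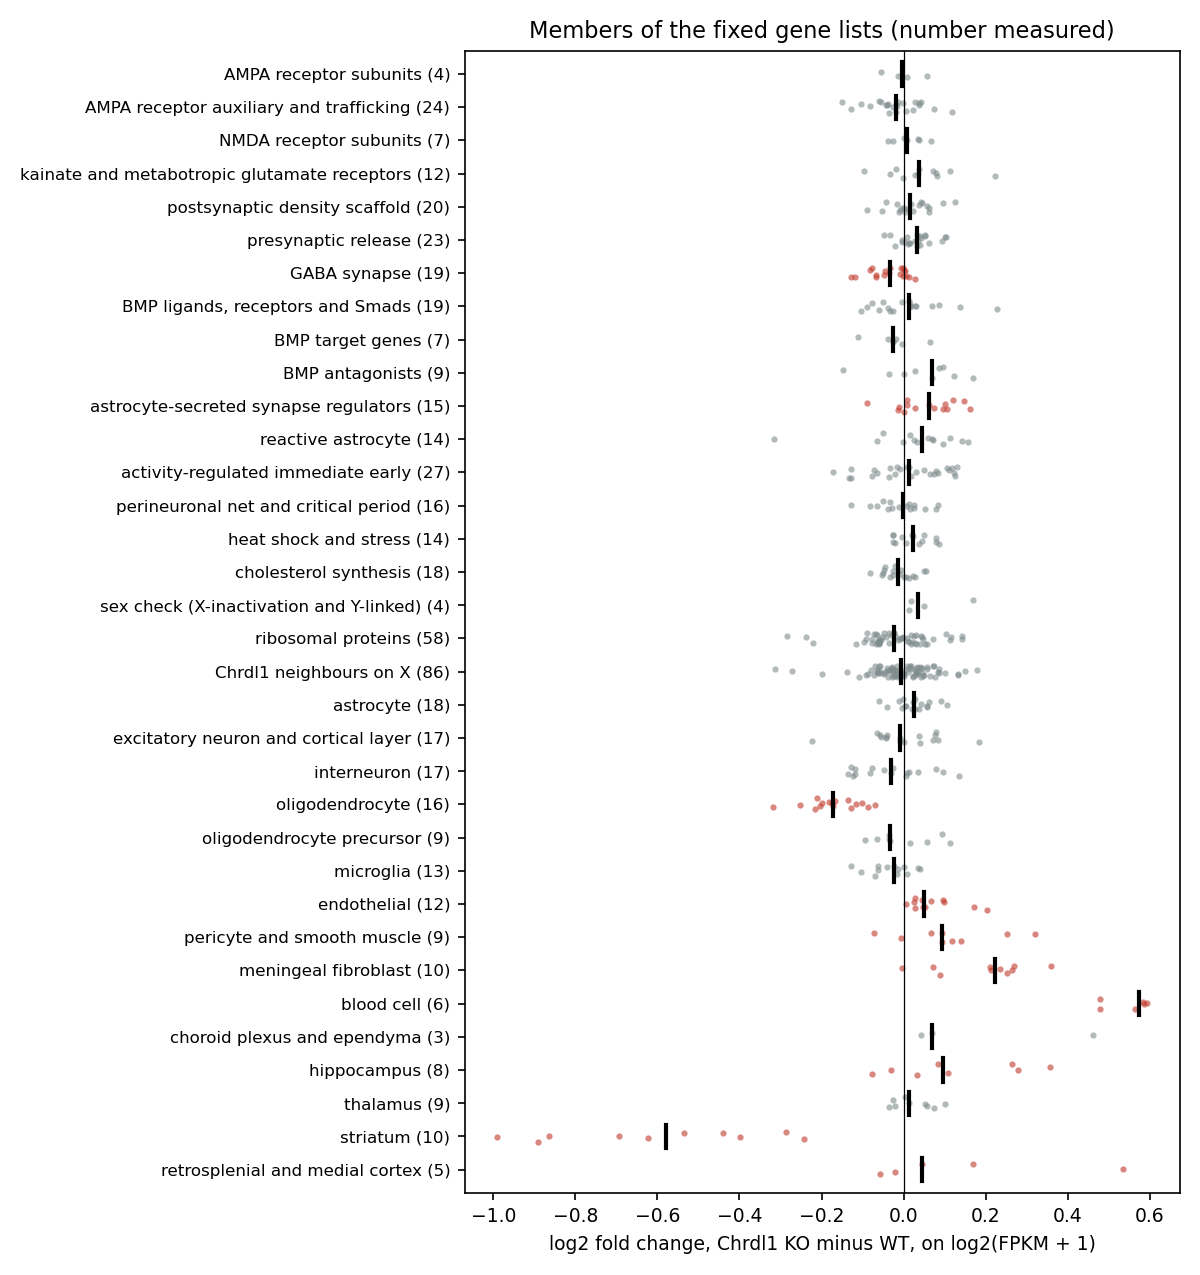
Log2 fold change (KO minus WT, log2(FPKM + 1), horizontal axis) of each measured member of the fixed lists (points, with the number measured in parentheses), with bars at the list medians and red for the lists called by camera at the preset correlation. The striatal list lies lowest, with a median of -0.58, the meningeal list is at 0.22, and the median of the AMPA receptor subunits is 0.00.

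Markers of striatal neurons were lower as a group in KO. All 10 measured members were lower, with a median log2 fold change of -0.58 and a camera adjusted p of 4.41e-19. The adjusted p was 0.291 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 0 passed without the block and 10 with it. *Tac1*, a neuropeptide precursor gene, measured 32.0 ± 3.01 FPKM in WT and 26.2 ± 3.71 in KO (SD, n = 3). The libraries did not share this difference: the median within pairs was -1.08 for number 1, 0.00 for number 2 and -0.71 for number 3. *Ppp1r1b*, which encodes DARPP-32 and was singled out after its values were seen, stood at 103, 91.7 and 81.1 FPKM in WT replicates 1, 2 and 3 and at 31.8, 101.4 and 35.9 in KO. Without KO replicate 2, *Ppp1r1b*, *Scn4b* (not on this list) and *Penk* were called as well, with log2 fold changes of -1.41, -1.89 and -1.35. In that library these genes were not lower than in WT replicate 2, so leaving it out favours such calls and they add no support.

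Markers of mature oligodendrocytes were also lower as a group, with all 16 members lower, a median of -0.17 and a camera adjusted p of 0.000207 (adjusted p = 0.766 with an estimated correlation). None passed alone. *Mbp*, the myelin basic protein gene, measured 1138 ± 249 FPKM in WT and 973 ± 302 in KO, and *Gjb1* 3.95 ± 1.44 and 2.95 ± 1.03. Within pairs the median was -0.26, 0.19 and -0.49, lower in the pairs numbered 1 and 3, as for the striatal markers. It was 0.07 without KO replicate 1 and 0.035 with the mean of the striatal markers as a covariate. Of 9 precursor markers 0 were called (*Gpr17* 0.11, *Cspg4* 0.09), and the median of that list, -0.03, differed in sign from its mean and its test.

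Markers of meninges and vessels were higher as groups in KO. The meningeal fibroblast list had 9 of 10 members higher, a median of 0.22 and a camera adjusted p of 2.64e-10, and the adjusted p was 0.291 with an estimated correlation. *Fmod*, an extracellular matrix gene, measured 6.59 ± 0.986 FPKM in WT and 8.69 ± 0.425 in KO, and the collagen gene *Col1a2* 6.96 ± 0.299 and 8.38 ± 0.896. Adjusted over the list alone, 0 members passed without the block and 4 with it, and the median within pairs was 0.34, -0.03 and 0.22. The 12 endothelial genes were all higher, with a median of 0.05 (adjusted p = 0.00628, and adjusted p = 0.291 with an estimated correlation; *Cdh5* 0.17, *Flt1* 0.20). The 9 measured pericyte and smooth muscle genes had a median of 0.09 (adjusted p = 0.000801, and adjusted p = 0.291 with an estimated correlation; *Tagln* 0.25, *Anpep* 0.14).

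The 6 measured blood cell genes were higher as a group (adjusted p = 4.95e-05, and adjusted p = 0.484 with an estimated correlation), which rested on KO replicate 2. *Hbb-bs*, an adult beta globin gene, measured 20.3 FPKM there and 4.2 to 5.4 in the other 5 libraries, and without that library the median of 0.57 became 0.03. The rows of *Hbb-bt* and *Hbb-b2* (each 0.48) held the same values and are uncertain as separate genes. Those of *Hbb-bs* and *Hbb-b1* (20.3 and 20.6 FPKM in KO replicate 2) and of *Hba-a1* and *Hba-a2* (9.9 and 9.4) were close to each other. The 6 rows are thus not independent measurements, and the camera p at the preset correlation overstates their evidence. The hippocampal list was higher with a median of 0.10 (adjusted p = 0.0441, 0.0649 with the block, and adjusted p = 0.669 with an estimated correlation), and the median was 0.04 without KO replicate 3 and -0.02 with the striatal covariate. With the block, 1 member, *Fibcd1* (0.26), was called adjusted over the list alone, and *C1ql2* was at 0.36.

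The retrosplenial and medial cortex list of 5 genes was higher as a group by camera (median 0.05, adjusted p = 0.0297, and adjusted p = 0.291 with an estimated correlation). This rested mainly on *Tshz2*, a zinc finger transcription factor gene, at 12.3 ± 2.05 FPKM in WT and 18.2 ± 1.55 in KO, higher in 3 of 3 pairs. Its log2 fold change was 0.53 (SE 0.13), and its adjusted p by limma was 1 over all genes, 0.235 with the block, and 0.0145 adjusted over the list alone. With voom on recovered reads and the block it was called (0.56, adjusted p 0.0167). *Cbln1* was at 0.17, and with the block 2 members were called adjusted over the list alone. Camera called none of the lists of 17 excitatory neuron (*Scnn1a* 0.18, *Foxp2* -0.22), 17 interneuron (*Gad2* -0.12, *Dlx5* -0.12), 13 microglia (*Ctss* -0.13, *Tyrobp* -0.10), 9 thalamus (*Slc17a6* 0.10, *Ramp3* 0.07) and 3 choroid plexus and ependyma genes (*Foxj1* 0.04, *Ccdc153* 0.07). In the excitatory neuron list the median, -0.01, and the test differed in sign. Over the 34 lists, camera called 10 at the preset correlation, 7 higher and 3 lower, and 0 with an estimated correlation, and fry called 0.

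**Figure D3:**
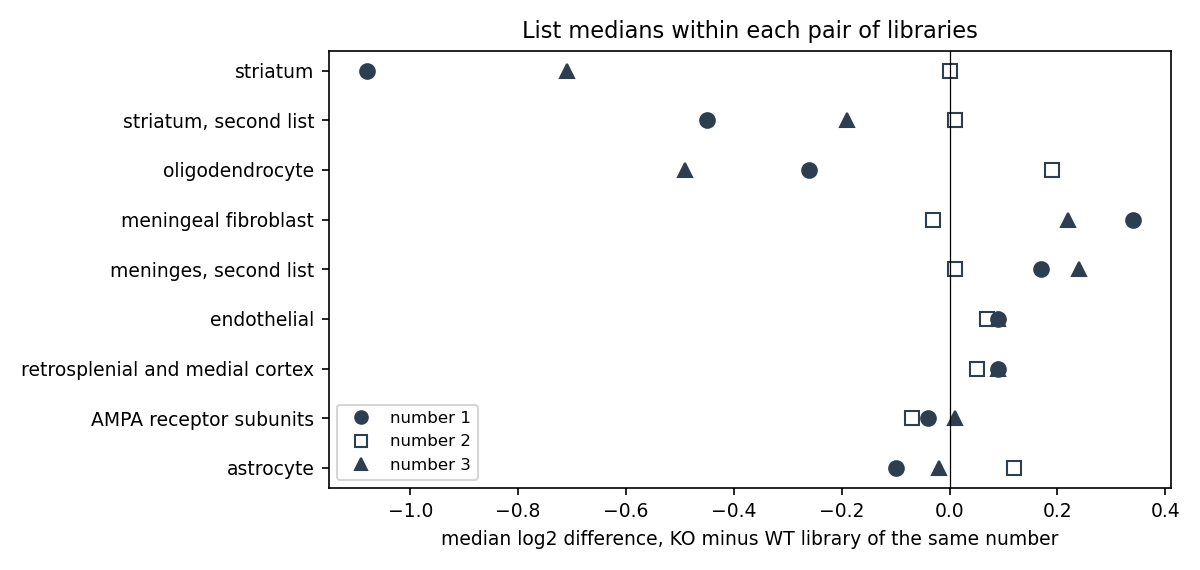
Median log2 difference between the KO and the WT library with the same title number (horizontal axis) for 9 lists, 2 of which were added after seeing the data. For the striatal list number 2 lies at 0.00 and numbers 1 and 3 at -1.08 and -0.71, and for the meningeal list number 2 lies at -0.03 and the others at 0.34 and 0.22.

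The other genes that the rule names had the smallest unadjusted p without overlap between genotypes, and none passed the correction (limma adjusted p of 1 for each). Without overlap a gene must have the same direction in 3 of 3 pairs, so that direction adds no support. Those higher in 3 of 3 pairs included *Cox7a1*, a cytochrome oxidase subunit gene (2.13 ± 0.166 and 2.94 ± 0.209 FPKM), *Myoc* (6.23 ± 0.803 and 8.35 ± 0.921), *Efemp1* (0.30), *Osr1* (0.29), *Lbp* (0.38) and *Bvht* (0.34). Those lower in 3 of 3 pairs included *Ipw*, a noncoding RNA of an imprinted locus (1.55 ± 0.131 and 0.764 ± 0.155), *Tmem215* (5.34 ± 0.202 and 4.24 ± 0.045) and *Acy3* (-0.30). Rows of small RNA genes (*Mir5128*, *Mir130c*, *Mir7082*, *Mir22* and *Snord53*) also met the rule, with log2 fold changes of 1.20, 0.47, -0.54, -0.36 and -1.70. These rest on few reads: *Mir5128*, with 35 bp, held 1, 0 and 0 reads in WT and 2, 2 and 1 in KO, and *Snord53*, also with 35 bp, 2, 4 and 2 in WT and 0 in each KO library. The other 3 held between 4 and 25 reads per library. Some of the longer genes named above also rest on few reads. *Cox7a1* held 28, 23 and 25 in WT and 29, 25 and 31 in KO. *Ipw* held 44, 28 and 41 in WT and 15, 15 and 14 in KO.

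Libraries grouped by title number and not by genotype. Pearson's r across genes, which are not independent replicates, was 0.9954 to 0.9965 between libraries with the same number and 0.9845 to 0.9929 between libraries of the same genotype. Between libraries that shared neither it was 0.9854 to 0.9917, within the range of the same genotype. The first principal component held 53.6% of the variance and separated number 2 from number 3.

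**Figure D4:**
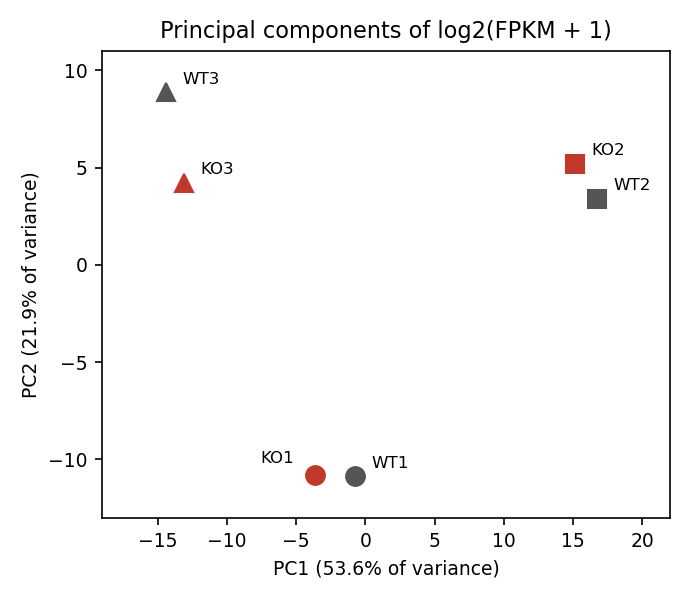
Principal components of log2(FPKM + 1) for the 6 libraries, with symbols for the title number and colours for genotype. The first component (53.6% of the variance) separates the libraries numbered 2 from those numbered 3, and each KO library lies nearest to the WT library with its number.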

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

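Settings added after seeing the data were voom on recovered reads, rows under 200 bp left out, both libraries of a number left out, the striatal covariate, and the estimated correlation with the block. *Chrdl1* was lower in every setting that tested it, and the mean filter of 5 FPKM removed it. The count of 1 called gene became 2 (2 lower) with a pseudocount of 0.1, which added *Snord53*, 6 (2 higher, 4 lower, the others being microRNA rows) with no filter, 0 (0 lower) with the filter of 5 FPKM, where fewer genes were tested, and 2 (1 higher, *Tshz2*) with voom and the block. It was 0 (0 lower) with both libraries numbered 1 or both numbered 2 left out, where fewer libraries were tested, and the log2 fold change of *Chrdl1* was then -1.91 and -1.93. Leaving out 1 library gave 1 to 4 calls (1 to 4 lower): 2 without WT replicate 2, *Snord53* added, and 4 without KO replicate 2. The 81 genes at unadjusted p under 0.05 became 344 with no filter, 215 at 0.1 FPKM, 34 at 5 FPKM, 305 with array weights, 503 with the replicate block, 536 with voom and the block, 29 and 208 with numbers 1 and 2 left out, and 241 with the striatal covariate, and ranged from 63 to 207 with 1 library left out. Beyond the pair differences that the main fit leaves in its error, the cause was not tested. The 10 called lists became 6 with no filter, 6 at 0.1 FPKM, 5 at 5 FPKM, 5 with the striatal covariate, and 0 with the estimated correlation, with that and the block, and with fry. With 1 library left out they ranged from 7 to 12. The median of the immediate early list, whose test pointed down and was not called, was 0.162 with array weights, 0.179 without WT replicate 3 and 0.083 with both numbered 3 left out, called higher in each, and ranged from -0.117 to 0.179 with 1 library left out. It was called lower without WT replicate 1 (-0.111), without KO replicate 3 (-0.117), with both numbered 1 left out (-0.046) and with the covariate (-0.117). Other lists that turned were oligodendrocyte (0.035 with the covariate, -0.398 to 0.068 with 1 library left out, highest without KO replicate 1), blood cell (0.034 to 0.983, where only the test turned, without KO replicate 2), GABA synapse (0.048 with the covariate) and hippocampus (-0.024 with the covariate, 0.037 to 0.169 with 1 library left out, where only the test turned, without KO replicate 3). The block changed no other call than those given beside the results. Of 2579 values of named genes, 77 changed sign, 3 gained a call and 0 called values reversed. Depth limits genes near 1 FPKM most, and within each pair the KO library was the shallower one.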

Other observations

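The tests that asked whether the striatal and the meningeal difference had the same size in every pair were chosen after values per library had been seen, and the second gene lists and the genes named here without a rule were chosen after seeing the data.

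Some transcripts differed between title numbers by more than between genotypes. *Arc*, which encodes a synaptic plasticity protein, measured 33.0, 56.0 and 86.6 FPKM in WT replicates 1, 2 and 3 and 39.1, 61.0 and 74.5 in KO, and *Fos* measured 14.4, 20.3 and 37.1 in WT and 19.9, 20.6 and 31.5 in KO. *Meg3*, a long noncoding RNA, stood at 105.4, 200.7 and 80.9 FPKM in WT and at 77.7, 169.3 and 52.4 in KO, lower in 3 of 3 pairs, with a limma adjusted p of 1 and 0.611 with the block. *Snhg11* stood at 83.3, 153 and 71 in WT and at 65.5, 135 and 46.7 in KO. *Grin2b* was 5.08 times higher in the libraries numbered 2 than in those numbered 3. *Ttr*, a choroid plexus transcript, followed neither number nor genotype: it was high in WT replicate 1 (149.6 FPKM) and KO replicate 3 (309.9) and between 2.9 and 5.5 in the other 4 libraries.

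The lower striatal markers in KO may reflect less striatal tissue in some KO dissections. A second list of 23 measured striatal genes, none of them on a fixed list, had a median log2 fold change of -0.20, below the range of -0.02 to 0.03 that holds 95% of 10000 random lists matched on mean expression, and pair medians of -0.45, 0.01 and -0.19. Random lists ignore that such markers move together. Camera with an estimated correlation was chosen after the result was seen. Over the 3 second lists it gave the second striatal list an adjusted p of 0.0543, and 0.242 with the block. This list was measured in the same libraries, and a genotype effect on striatal genes would lower it too. It therefore cannot tell less striatal tissue from such an effect, and less striatal tissue stays open. In the pair numbered 2 the median of the fixed list was 0.005. That is 1 library per genotype with no error estimate, so it cannot decide about a genotype effect of the same size in every pair. To ask about the lower depth of the KO libraries, all libraries were thinned to equal reads, and the median was then -0.576. FPKM is already scaled by depth, so thinning was bound to move the median little, and it cannot decide about depth. The most abundant markers were *Ppp1r1b* (91.7 FPKM in WT replicate 2, 101.4 in KO replicate 2, 31.8 in KO replicate 1) and *Penk* (77.2, 82.3 and 27.4), and 9 of the 10 genes kept 1 FPKM or more in every library, while a genotype effect that varies between animals stays open too.

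The higher meningeal markers in KO may likewise reflect more meninges on some KO samples. A second list of 23 measured meningeal genes, 1 of them also on a fixed list, had a median of 0.13, above the range of -0.03 to 0.04 of the random lists. Its adjusted p by camera with an estimated correlation was 0.0393, and 0.242 with the block. A genotype effect on meningeal genes would raise this list too. It therefore cannot tell more meninges from such an effect, and more meninges stays open. The median in the pair numbered 2 was -0.031, again 1 library per genotype without an error estimate. It cannot decide about an effect of the same size in every pair. The most abundant markers were *Igfbp2* (51.9, 37.7 and 40.9 FPKM in WT, 55.4, 40.9 and 41.0 in KO) and *Igf2* (35.7, 35.7 and 37.1 in WT, 49.5, 35.6 and 47.4 in KO). A genotype effect on meningeal cells that varies between animals stays open.

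The grouping of libraries by title number could come from a technical difference between pairs that acts on transcript length. Across genes, which are not independent replicates, the difference between numbers 2 and 3 correlated with exon length at a Spearman rho of 0.34 in KO and 0.51 in WT. With GC content the rho was -0.28 and -0.20. Such correlations also lay within pairs: KO minus WT had a rho with length of 0.13, -0.22 and 0.25 for numbers 1, 2 and 3. With GC content it was 0.31, -0.13 and -0.03. For the mean KO minus WT difference the rho was 0.12 with length and 0.10 with GC content. What the numbers stand for, such as a litter or a day, was not tested, and no biological explanation was tested.

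The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene, as did 1 other split, for 2 of 10 splits with as many, and the highest of the others was 1. For lists the real split called 10, the highest other was 13, and 3 of the 10 splits gave as many. Among the 4 splits that part all 3 pairs, the blocked fit called 1 gene in the real split and 1, 1 and 0 in the others. A split that put WT replicates 1 and 2 with KO replicate 2 gave 2782 genes at a limma unadjusted p under 0.05, against 81. It sets both libraries numbered 2 against both numbered 3, unlike the real split, and points to a structure of the samples other than genotype. The other splits that part all 3 pairs gave 40, 109 and 65 such genes, and 415, 1128 and 506 with the block, against 503 in the real split.

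The second list of 8 measured retrosplenial genes had a median log2 fold change of 0.02, within the range of -0.04 to 0.05 of the random lists, while *Tshz2* was at 0.53. Of its members 4 were higher and 4 lower, from -0.13 (*Synpr*) to 0.30 (*Ctxn3*). With the block 2 had a limma unadjusted p under 0.05, *Ctxn3* and *Zfpm2* (0.24). *Nr4a2* on this list is also on fixed lists.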
